A study of Homo sapiens with 60 samples.

How the data were processed

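RNA of 3 human acute myeloid leukaemia cell lines was measured on 60 arrays after 48 h with vehicle, azacytidine, panobinostat or both, in 12 groups of 5 biological replicates. Per the labels' protocols, RNA was extracted with Trizol and 100 ng was labelled with the GeneChip WT Plus kit for an Affymetrix gene array. Per the submitters' processing notes, the deposited log2 values were made by the authors with RMA in Affymetrix Expression Console, with no versions given. The value table held 53617 rows from 1.48 to 14.2, and array medians lay at 5.259 to 5.304 in MV4;11, 5.452 to 5.531 in AML-193 and 5.618 to 5.66 in THP-1. Levels were therefore compared only within lines, and lines were compared only by their drug effects. Whether the arrays of the lines were normalised together is not stated.

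The table of probe names gave 16098 rows 1 gene symbol and none several, which made 14884 genes. The other 37519 rows were not named here and were left out of the comparisons of genes. For the 779 genes with several rows, the row with the highest mean over all arrays was used. A gene was tested in a line if it lay above the 30th percentile of the array on at least 5 of the line's 20 arrays. This left 12818 genes in MV4;11, 12796 in AML-193 and 12974 in THP-1.

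Each line was fitted with limma 3.58.1 in R 4.3.3 as 4 groups with 16 residual degrees of freedom. The comparisons were each drug and the combination against vehicle, the combination against each drug alone, and the departure from additivity, which is the combination minus both single drugs plus vehicle. Line differences of the combination effect came from a fit of the arrays of both lines. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, and a gene was called changed below 0.05. The tables were handled with data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

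Gene lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. Of 30 lists, 28 had at least 3 measured members and were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry's directional test were alternatives. The lists were cancer-testis and germline genes, interferon-stimulated genes, HLA class I and antigen processing genes, HLA class II genes, DNA methylation enzymes and readers, histone deacetylase genes, p53 target genes, mitosis genes, DNA replication genes, homologous recombination and Fanconi genes, and MYC targets and ribosome biogenesis genes. They further held HOXA cluster and MLL-fusion target genes, monocyte and macrophage genes, granulocyte genes, stem and progenitor cell genes, erythroid and megakaryocyte genes, T, B and NK lymphocyte genes, fibroblast, endothelial and epithelial genes, neuron genes, replication-independent histone genes, and metallothionein genes. The remaining lists were pro-apoptotic genes, anti-apoptotic genes, integrated stress and unfolded protein response genes, heat shock genes, genes methylated and silenced in leukaemia, inflammatory and NF-kappa-B genes, AP-1 and immediate early genes, cholesterol synthesis genes, and nucleoside uptake and metabolism genes. Counts of members adjusted over the list alone are given beside the counts over all genes. Up to 4 members with the smallest p in the direction of a called list are named, except for the called lists given by counts alone.

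For a comparison against vehicle, the genes named were the 10 with the largest rise and the 10 with the largest fall among changed genes whose 5 treated arrays all lay on 1 side of the 5 vehicle arrays. For other comparisons they were the first 5 in each direction, for genes shared by the lines 10 in each direction, and for line differences the first of 5 in each direction. Uncharacterised loci, small nucleolar RNAs and microRNAs were passed over. PRAME was named as the member of an uncalled list after its values were seen.

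The alternatives were no filter, a filter at the 50th percentile, median centring, cyclic loess between arrays, only the groups compared, all 60 arrays in 1 fit, the replicate number as a block, a trended and robust variance, array weights, the mean of a gene's rows, and each array left out in turn. For each comparison 100 groupings, the real one included, were fitted. They were splits of the arrays of both groups for a drug comparison, random assignments of deviations from additivity to the arrays for a departure, and random line labels within a treatment for a line difference, with the mean of each gene over a line's vehicle and combination arrays taken off first. Overlaps of comparisons that share vehicle arrays were set beside 100 simulations of unchanged groups and beside 20 splits of the vehicle arrays.

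The procedure was tested on simulated data in which 200 genes of the azacytidine group were changed by known amounts. At a log2 size of 0.25, 46% were called in the right direction in MV4;11, 36% in AML-193 and 50% in THP-1. At 0.5 these were 100%, 96% and 94%, and at 1 and 2 they were 100% in each line. False calls numbered 9, 5 and 19. A mitosis list shifted by -0.2 was called in each line, with 0, 1 and 0 other lists called. The simulated genes varied independently of one another, so this does not show how the list tests behave for correlated genes. The number of arrays limits the precision of all values.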

Results

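Gene expression was measured in 3 human acute myeloid leukaemia cell lines treated for 48 h with azacytidine, panobinostat or both. MV4;11 is a myelomonocytic leukaemia line with a rearranged MLL gene, AML-193 is a monocytic leukaemia line grown with GM-CSF, and THP-1 is a monocytic leukaemia line with a rearranged MLL gene. Azacytidine is a cytidine analogue that is built into RNA and DNA and traps DNA methyltransferases. Panobinostat is a hydroxamate inhibitor of histone deacetylases. The comparisons ask how each drug changed each line, whether the pair departed from the sum of the single drugs, and whether the lines differed. Each line had 4 groups of 5 biological replicates, which gave 60 arrays. Vehicle cells received 0.1% DMSO. MV4;11 received 0.5 µM azacytidine and 1.5 nM panobinostat, AML-193 received 5 µM and 5 nM, and THP-1 received 3 µM and 5 nM. The value table held log2 intensities for 53617 rows, and the number of arrays limits the precision. The median correlation of an array with the other arrays of its group lay between 0.9922 and 0.9957. The p-values measure the spread between these samples. Expression changes are log2 fold changes ± standard error from limma, with 5 arrays per group.

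The drug targets themselves changed little. HDAC6, a cytoplasmic deacetylase of tubulin, fell with panobinostat in MV4;11 (-0.23 ± 0.05), AML-193 (-0.27 ± 0.06) and THP-1 (-0.23 ± 0.04), with limma adjusted p of 0.00162, 0.00232 and 4.3e-04. In MV4;11, HDAC1 (0.16 ± 0.04) and HDAC2 (0.18 ± 0.04) rose with panobinostat, though HDAC2 did not pass with the mean of its rows (adjusted p = 0.606). HDAC3 passed in 1 comparison against vehicle, the combination in THP-1 (0.17 ± 0.05, adjusted p = 0.00802). DNMT1, the maintenance DNA methyltransferase, rose with azacytidine in THP-1 (0.18 ± 0.04) and fell there with panobinostat (-0.33 ± 0.04) and with the combination (-0.18 ± 0.04). Its vehicle level in THP-1 was 9.73 ± 0.06 (SD, n = 5). DNMT1 did not pass in MV4;11, where its change with azacytidine was -0.10 ± 0.04 (adjusted p = 0.164), nor in AML-193, where its change was -0.05 ± 0.07 with azacytidine (adjusted p = 0.741) and -0.10 ± 0.07 with panobinostat (adjusted p = 0.289). The latter passed as a fall without Pan replicate 5 (adjusted p = 0.0141), with array weights (0.0132) and without both Control replicate 1 and Pan replicate 5 (0.00164). DNMT3B rose with panobinostat in AML-193 (0.45 ± 0.09, adjusted p = 9.0e-04). DNMT3A fell with the combination in MV4;11 (-0.20 ± 0.06) and AML-193 (-0.24 ± 0.05) and rose in THP-1 (0.18 ± 0.04). CDKN1A was not among the genes named here.

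**Figure D1:**
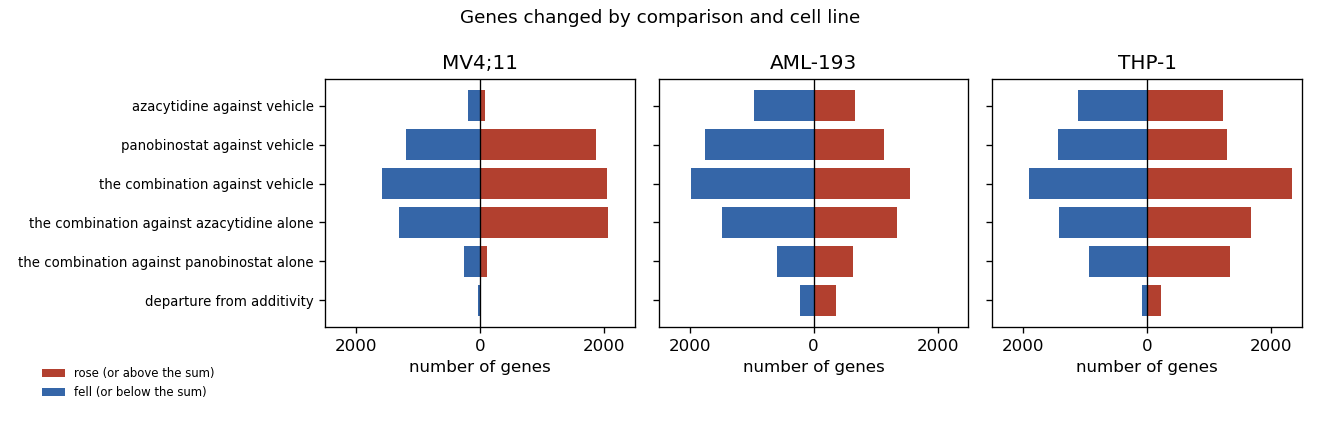
Number of genes that rose (right) and fell (left) in each line for the 5 drug comparisons and the departure from additivity, limma adjusted p below 0.05, 5 arrays per group. Azacytidine changed 284 genes in MV4;11 (0.5 µM), 1627 in AML-193 (5 µM) and 2333 in THP-1 (3 µM).

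Azacytidine changed few genes in MV4;11, all by less than 2-fold. The largest rises were RGS16 (0.59 ± 0.07), a regulator of G-protein signalling, GCH1 (0.53 ± 0.08), the first enzyme of tetrahydrobiopterin synthesis, CES1 (0.51 ± 0.10), TKTL1 (0.48 ± 0.10) and HAL (0.47 ± 0.06). They were followed by CCL2 (0.45 ± 0.08), a monocyte chemoattractant, RPP21 (0.45 ± 0.09), GPR183 (0.39 ± 0.08), PLK2 (0.39 ± 0.08) and FAM120AOS (0.38 ± 0.05). The largest falls were PDGFA (-0.57 ± 0.08), a growth factor, ATF3 (-0.56 ± 0.09), a stress-induced transcription factor, CD109 (-0.52 ± 0.06), RASA3 (-0.51 ± 0.04) and KRTAP10-2 (-0.50 ± 0.10). CNTN4 (-0.47 ± 0.08), IPCEF1 (-0.44 ± 0.06), R3HDM2 (-0.41 ± 0.04), RUFY3 (-0.39 ± 0.09) and IRF4 (-0.38 ± 0.07) came next. In all, 284 of 12818 tested genes changed, 85 rising and 199 falling. Integrated stress and unfolded protein response genes fell as a group, 4 of 21 measured members (6 adjusted over the list alone), with ATF3, WARS1 (-0.25 ± 0.05), CARS1 (-0.20 ± 0.05) and CBS (-0.16 ± 0.04) first and camera adjusted p = 4.9e-07. Of 17 measured p53 target genes, 4 rose (5 adjusted over the list alone), namely SPATA18 (0.36 ± 0.07), SESN1 (0.22 ± 0.05), TRIAP1 (0.24 ± 0.06) and EDA2R (0.20 ± 0.05), with camera adjusted p = 3.0e-04. DNA replication genes were called upward (camera adjusted p = 2.5e-04) although 1 of 25 passed, CCNE2 (0.28 ± 0.05) (2 adjusted over the list alone), and with an estimated correlation the adjusted p was 0.0561. AP-1 and immediate early genes were called downward, where 4 of 27 fell (6 adjusted over the list alone) and 1 rose, with camera adjusted p just under 0.05, and adjusted p = 0.31 with an estimated correlation. A call upward went to inflammatory and NF-kappa-B genes, where 2 of 21 rose (4 adjusted over the list alone), with camera adjusted p = 0.0301, and adjusted p = 0.239 with an estimated correlation. Mitosis genes were called upward, where 0 of 34 rose (0 adjusted over the list alone), with camera adjusted p = 0.0224, and adjusted p = 0.239 with an estimated correlation. EDA2R did not pass with no filter (adjusted p = 0.062), median centring (0.0712), only the 2 groups compared (0.127) or all 60 arrays in 1 fit (0.289). CBS did not pass with the last 2 of these (0.103 and 0.0853) or a trended, robust variance (0.116), CARS1 (0.102) and PLK2 (0.0538) with only the 2 groups compared, and WARS1 with the mean of its rows (0.145). With each of the 10 arrays left out in turn, TRIAP1 did not pass in 9 fits, EDA2R and CBS in 8, CARS1 in 6, SESN1 in 5 and RUFY3 in 4. The count of changed genes fell, to 167 to 228, with any 1 array left out. It was 167 and 169 without Control replicates 1 and 3, and 184, 170 and 172 without Aza replicates 1, 2 and 5. It varied by fit, at 138 with only the 2 groups compared, 514 with all 60 arrays in 1 fit and 482 with a trended, robust variance.

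Panobinostat changed 23.9% of the genes tested in MV4;11. VAT1L (2.69 ± 0.05) and TMT1B (2.08 ± 0.05), a thiol methyltransferase, rose most, followed by CCL2 (1.72 ± 0.08), GPRIN3 (1.39 ± 0.15) and GPR65 (1.37 ± 0.06), a proton-sensing receptor. DHRS3 (1.36 ± 0.09), a retinaldehyde reductase, BMP2 (1.29 ± 0.12), GPC3 (1.29 ± 0.08), TLR6 (1.24 ± 0.12) and RGS1 (1.23 ± 0.12) also rose by more than 2-fold. The largest falls were CXCL8 (-1.54 ± 0.15), the neutrophil chemoattractant interleukin-8, ALOX12 (-1.54 ± 0.06), a lipoxygenase, TREM2 (-1.23 ± 0.13), PDGFA (-1.20 ± 0.08) and CXCL10 (-1.17 ± 0.12). Falls of GAS6-DT (-1.14 ± 0.16), KLF2 (-1.12 ± 0.09), IFIT3 (-1.11 ± 0.15), IFI44 (-1.07 ± 0.13) and TNF (-1.03 ± 0.07) came next. Of 12818 genes, 1868 rose and 1199 fell, 19 and 10 of them by 2-fold or more. Mitosis genes fell in 22 of 34 members (23 adjusted over the list alone), with KIF2C (-0.43 ± 0.05), CCNB2 (-0.31 ± 0.04), PLK1 (-0.26 ± 0.04) and CDC20 (-0.33 ± 0.05) first and camera adjusted p = 2.3e-08, while 2 members rose. MYC targets and ribosome biogenesis genes rose in 18 of 26 (21 adjusted over the list alone), led by NOP16 (0.34 ± 0.05), PPAT (0.28 ± 0.04), NOLC1 (0.27 ± 0.04) and ATIC (0.25 ± 0.04), with camera adjusted p = 2.3e-08. Interferon-stimulated genes rose in 4 and fell in 15 of 35 (15 adjusted over the list alone), with XAF1 (-0.87 ± 0.05), IRF9 (-0.77 ± 0.06), IFIT2 (-0.66 ± 0.08) and IFI44L (-0.88 ± 0.11) first. Their camera adjusted p was 3.9e-04, and adjusted p = 0.161 with an estimated correlation. Inflammatory and NF-kappa-B genes rose in 3 and fell in 9 of 21 (10 adjusted over the list alone), TNF, CXCL8, CXCL10 and RELB (-0.71 ± 0.08) first, with camera adjusted p = 0.00214, and adjusted p = 0.136 with an estimated correlation. Cholesterol synthesis genes were called downward, where 7 of 17 fell (9 adjusted over the list alone), with camera adjusted p = 0.00799, and adjusted p = 0.362 with an estimated correlation. A call downward went to integrated stress and unfolded protein response genes, where 12 of 21 fell (13 adjusted over the list alone) and 4 rose, with camera adjusted p = 7.2e-04, and adjusted p = 0.0549 with an estimated correlation.

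The combination in MV4;11 moved most of the genes that led with panobinostat. VAT1L (2.97 ± 0.05), TMT1B (2.50 ± 0.05), GPRIN3 (1.98 ± 0.15), GPC3 (1.82 ± 0.08) and CCL2 (1.58 ± 0.08) rose most. BMP2 (1.49 ± 0.12), GPR65 (1.45 ± 0.06), MNDA (1.41 ± 0.14), a myeloid nuclear protein, WDR17 (1.35 ± 0.12) and DHRS3 (1.34 ± 0.09) followed. CXCL8 (-2.23 ± 0.15), ALOX12 (-2.08 ± 0.06), PDGFA (-1.71 ± 0.08), KLF2 (-1.66 ± 0.09) and TNF (-1.33 ± 0.07) fell most. CXCL10 (-1.25 ± 0.12), TRIB3 (-1.20 ± 0.10), a stress-induced pseudokinase, MCEMP1 (-1.19 ± 0.09), KLF6 (-1.18 ± 0.08) and IFIT3 (-1.17 ± 0.15) followed. Altogether 2051 genes rose and 1578 fell. Integrated stress and unfolded protein response genes rose in 1 and fell in 14 of 21 (14 adjusted over the list alone), with ATF5 (-0.98 ± 0.07), DDIT4 (-1.02 ± 0.07), TRIB3 and ATF3 (-1.13 ± 0.09) first and camera adjusted p = 1.5e-08. Cholesterol synthesis genes fell in 14 of 17 (14 adjusted over the list alone), with a median of -0.34 and camera adjusted p = 5.5e-09. The first were ACAT2 (-0.53 ± 0.04), HMGCS1 (-0.72 ± 0.06), which makes HMG-CoA, IDI1 (-0.44 ± 0.04) and INSIG1 (-0.54 ± 0.06). Inflammatory and NF-kappa-B genes fell in 12 of 21 (13 adjusted over the list alone), with camera adjusted p = 1.2e-04, and 2 rose. AP-1 and immediate early genes rose in 4 and fell in 13 of 27 (13 adjusted over the list alone), among them FOS (-1.09 ± 0.06) and KLF10 (-0.66 ± 0.04), with camera adjusted p = 1.2e-04, and adjusted p = 0.0622 with an estimated correlation. p53 target genes fell in 2 and rose in 11 of 17 (11 adjusted over the list alone), with EDA2R (0.88 ± 0.05), SESN1 (0.63 ± 0.05), TRIAP1 (0.55 ± 0.06) and TP53INP1 (0.36 ± 0.05) first and camera adjusted p = 0.0015. Nucleoside uptake and metabolism genes fell in 2 and rose in 7 of 16 (8 adjusted over the list alone), TYMS (0.26 ± 0.04) and DHODH (0.43 ± 0.06) first, with camera adjusted p = 0.0416, and adjusted p = 0.117 with an estimated correlation. MYC targets and ribosome biogenesis genes rose in 19 of 26 (19 adjusted over the list alone), with camera adjusted p = 1.6e-07. DNA replication genes were called upward, where 14 of 25 rose (15 adjusted over the list alone) and 2 fell, with camera adjusted p = 0.00649, and adjusted p = 0.117 with an estimated correlation. Mitosis genes were called downward, where 10 of 34 fell (10 adjusted over the list alone) and 2 rose, with camera adjusted p = 0.00686, and adjusted p = 0.174 with an estimated correlation.

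Set against single drugs, the combination in MV4;11 lay close to panobinostat. It differed from azacytidine alone in 3379 genes, with VAT1L (2.96 ± 0.05), TMT1B (2.24 ± 0.05), GPC3 (1.62 ± 0.08), GPRIN3 (1.61 ± 0.15) and GPR65 (1.52 ± 0.06) highest and ALOX12 (-2.11 ± 0.06), CXCL8 (-1.98 ± 0.15), CXCL10 (-1.63 ± 0.12), KLF2 (-1.59 ± 0.09) and TNF (-1.56 ± 0.07) lowest. It differed from panobinostat alone in 377 genes, of which 118 were higher and 259 lower. Against panobinostat, TKTL1 (0.96 ± 0.10), C3orf80 (0.63 ± 0.10), VIT (0.62 ± 0.07), MNDA (0.62 ± 0.14) and PLAAT4 (0.61 ± 0.09) were higher. RGS1 (-0.88 ± 0.12), EGR1 (-0.83 ± 0.09), an immediate early transcription factor, OCSTAMP (-0.73 ± 0.09), EGR3 (-0.67 ± 0.12) and DDIT4 (-0.64 ± 0.07) were lower. The count against panobinostat was 171 with only the 2 groups compared and 601 with all 60 arrays in 1 fit. The combination departed from the sum of the single effects in 35 genes, 8 above the sum and 27 below it. CD109 (0.88 ± 0.09), CCDC50 (0.40 ± 0.07), TDRD10 (0.38 ± 0.07), PECR (0.38 ± 0.08) and LYNX1-SLURP2 (0.32 ± 0.06) lay above. RGS1 (-1.31 ± 0.17), OCSTAMP (-0.79 ± 0.12), EGR1 (-0.78 ± 0.12), TMEM114 (-0.78 ± 0.15) and RGS16 (-0.76 ± 0.10) lay below. Cholesterol synthesis genes lay below the sum as a group (median -0.235, camera adjusted p = 4.4e-16), with 3 of 17 passing (10 adjusted over the list alone), HMGCS1 (-0.62 ± 0.09), ACAT2 (-0.29 ± 0.05) and DHCR7 (-0.42 ± 0.08). Inflammatory genes also lay below it, with 4 of 21 passing (4 adjusted over the list alone), ICAM1 (-0.70 ± 0.10), TNF (-0.53 ± 0.09), CCL5 (-0.33 ± 0.06) and CCL2 (-0.58 ± 0.12), and camera adjusted p = 5.8e-06. AP-1 and immediate early genes were called below the sum, where 1 of 27 passed (4 adjusted over the list alone), with camera adjusted p = 3.5e-04, and adjusted p = 0.126 with an estimated correlation. Heat shock genes were called above the sum, where 0 of 13 passed (4 adjusted over the list alone), with camera adjusted p = 0.00244. A call above the sum went to interferon-stimulated genes, where 0 of 35 passed (5 adjusted over the list alone), with camera adjusted p = 3.4e-04, and adjusted p = 0.13 with an estimated correlation. p53 target genes were called above the sum, where 0 of 17 passed (2 adjusted over the list alone), with camera adjusted p = 0.0358, and adjusted p = 0.13 with an estimated correlation. With each of the 20 arrays left out in turn, LYNX1-SLURP2 did not pass in 17 fits, PECR in 15, CCL2 in 13, CCL5 in 12, TMEM114 in 7, TDRD10 in 5 and DHCR7 in 1. LYNX1-SLURP2 also did not pass with no filter (adjusted p = 0.056), and neither it nor TDRD10 passed with all 60 arrays in 1 fit (0.242 and 0.118) or a trended, robust variance (0.0924 and 0.148). The departure count fell, to 18 to 31, with any 1 array left out. It was 21 without Control replicate 5 and 20, 21 and 23 without Aza replicates 1, 2 and 3. Without Pan replicates 1, 3 and 4 it was 21, 23 and 18. It was 81 with all 60 arrays in 1 fit and 74 with a trended, robust variance.

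In AML-193, azacytidine lowered all 34 measured mitosis genes and raised monocyte, macrophage and inflammatory genes. The mitosis list had a median change of -0.59 and camera adjusted p = 1.7e-63, and 34 members passed adjusted over the list alone. KIF20A (-1.34 ± 0.07), a mitotic kinesin, PLK1 (-1.09 ± 0.05), the mitotic polo-like kinase, CCNB1 (-1.06 ± 0.05) and CDC20 (-0.98 ± 0.05) were among the largest falls of any gene, with KIF14 (-0.94 ± 0.05), PRR11 (-0.92 ± 0.05) and PTTG1 (-0.91 ± 0.11). CEACAM8 (-1.31 ± 0.14), AZU1 (-1.07 ± 0.05) and SLPI (-0.93 ± 0.06) were also among the largest falls. The largest rises were GPR34 (1.43 ± 0.11), SNAR-B1 (1.38 ± 0.14), a short non-coding RNA with near-identical copies and so uncertain, LRP2 (1.15 ± 0.05), EPB41L3 (1.14 ± 0.05) and GPR82 (1.14 ± 0.14). HBEGF (1.10 ± 0.08), an EGF-like growth factor, BCL2A1 (1.10 ± 0.05), an anti-apoptotic BCL2 relative, TTC14 (1.09 ± 0.08), CCL7 (1.08 ± 0.12) and AQP9 (1.08 ± 0.09) followed. In all, 664 of 12796 genes rose and 963 fell. Granulocyte genes rose in 1 and fell in 9 of 17 (9 adjusted over the list alone), with PRTN3 (-0.87 ± 0.08), proteinase 3, and MPO (-0.70 ± 0.07), myeloperoxidase, beside AZU1 and CEACAM8, and camera adjusted p = 2.3e-05. Monocyte and macrophage genes fell in 2 and rose in 9 of 24 (10 adjusted over the list alone), with S100A8 (0.79 ± 0.05), S100A9 (0.80 ± 0.06), TREM1 (0.88 ± 0.07) and EGR1 (0.75 ± 0.07) first and camera adjusted p = 3.2e-05. Inflammatory and NF-kappa-B genes rose in 6 of 21 (7 adjusted over the list alone), with CCL2 (0.81 ± 0.05), CXCL8 (0.63 ± 0.05), IER3 (0.64 ± 0.07) and CCL20 (0.74 ± 0.10) first and camera adjusted p = 2.7e-05. Cholesterol synthesis genes fell in 7 of 17 (8 adjusted over the list alone), with INSIG1 (-0.57 ± 0.05), SQLE (-0.41 ± 0.06), squalene epoxidase, SREBF2 (-0.27 ± 0.05) and DHCR7 (-0.20 ± 0.05) first and camera adjusted p = 3.2e-05. Anti-apoptotic genes fell in 2 and rose in 4 of 14 (6 adjusted over the list alone), with BCL2A1, PIM1 (0.58 ± 0.05) and MCL1 (0.33 ± 0.05) first, camera adjusted p = 0.0315, and adjusted p = 0.258 with an estimated correlation. HOXA cluster and MLL-fusion target genes fell in 3 of 14 (4 adjusted over the list alone), BCL2 (-0.48 ± 0.05), MYB (-0.27 ± 0.03) and CDK6 (-0.26 ± 0.06), with camera adjusted p = 0.0229, and adjusted p = 0.199 with an estimated correlation. DNA replication genes fell in 1 and rose in 9 of 25 (12 adjusted over the list alone), with MCM6 (0.30 ± 0.04), CDC45 (0.34 ± 0.05), CDC6 (0.42 ± 0.08) and CCNE2 (0.27 ± 0.05) first. Their camera adjusted p was 0.00234, and adjusted p = 0.258 with an estimated correlation. AP-1 and immediate early genes were called upward, where 7 of 27 rose (8 adjusted over the list alone), with camera adjusted p = 0.00124, and adjusted p = 0.0848 with an estimated correlation. A call downward went to interferon-stimulated genes, where 9 of 36 fell (10 adjusted over the list alone), with camera adjusted p = 0.0229, and adjusted p = 0.258 with an estimated correlation.

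Panobinostat in AML-193 raised interferon-stimulated genes and lowered granulocyte genes. Of 36 measured interferon-stimulated genes 30 rose (30 adjusted over the list alone), with a median of 0.72 and camera adjusted p = 1.8e-40. IFIT1 (2.31 ± 0.14), IFI44 (1.40 ± 0.05), RIGI (1.23 ± 0.05), the cytoplasmic RNA sensor RIG-I, EIF2AK2 (1.21 ± 0.04), the RNA-activated kinase PKR, and SAMD9L (0.93 ± 0.04) were among them. ENPP2 (2.36 ± 0.08), autotaxin, GPR65 (2.05 ± 0.07), ARID5B (1.88 ± 0.11), CCL7 (1.74 ± 0.12) and NBEAP1 (1.70 ± 0.22) also rose strongly. ADAM28 (1.62 ± 0.06), TREM1 (1.51 ± 0.07) and HSPA7 (1.47 ± 0.17) completed the 10 largest rises. The largest falls were PRTN3 (-2.30 ± 0.08), CEACAM8 (-2.01 ± 0.14), AZU1 (-1.76 ± 0.05), CEACAM6 (-1.74 ± 0.07) and RGCC (-1.35 ± 0.05). CFD (-1.31 ± 0.06), complement factor D, TMEM87A (-1.27 ± 0.05), NXF3 (-1.23 ± 0.07), LSAMP (-1.14 ± 0.08) and OLFM4 (-1.08 ± 0.07) followed. Of 12796 genes, 1136 rose and 1757 fell, 39 and 14 of them by 2-fold or more. Granulocyte genes fell in 9 of 17 (10 adjusted over the list alone), with camera adjusted p = 1.4e-04, and 2 rose. Monocyte and macrophage genes fell in 3 and rose in 11 of 24 (12 adjusted over the list alone), with TREM1, CD86 (1.25 ± 0.07), S100A9 (0.72 ± 0.06) and CCR2 (1.27 ± 0.10) first and camera adjusted p = 5.3e-04. Stem and progenitor cell genes rose in 5 of 24 (5 adjusted over the list alone), MMRN1 (1.24 ± 0.06) and EMP1 (0.81 ± 0.09) first, with camera adjusted p = 0.0114, and 2 fell. Homologous recombination and Fanconi genes fell in 10 of 14 (12 adjusted over the list alone), RAD54L (-0.35 ± 0.05) and BARD1 (-0.21 ± 0.05) first, with camera adjusted p = 8.5e-05, and adjusted p = 0.222 with an estimated correlation. DNA replication genes fell in 12 of 25 (12 adjusted over the list alone), TYMS (-0.34 ± 0.04), thymidylate synthase, first, with camera adjusted p = 1.4e-04, and adjusted p = 0.225 with an estimated correlation. AP-1 and immediate early genes were called upward, where 8 of 27 rose (8 adjusted over the list alone) and 2 fell, with camera adjusted p = 0.0229, and adjusted p = 0.306 with an estimated correlation. A call upward went to inflammatory and NF-kappa-B genes, where 7 of 21 rose (7 adjusted over the list alone) and 3 fell, with camera adjusted p = 0.0114, and adjusted p = 0.0575 with an estimated correlation. Mitosis genes were called downward, where 10 of 34 fell (12 adjusted over the list alone) and 1 rose, with camera adjusted p = 6.7e-04, and adjusted p = 0.32 with an estimated correlation.

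In AML-193 the combination raised interferon-stimulated genes and lowered mitosis genes. Among the 10 largest rises were 4 short RNAs of the SNAR family, SNAR-B1 (3.12 ± 0.14), SNAR-C1 (2.42 ± 0.15), SNAR-D (2.25 ± 0.17) and SNAR-H (2.13 ± 0.21). SNAR genes are near-identical copies, so their rows are uncertain as single genes. CCL7 (2.39 ± 0.12), a monocyte chemokine, ENPP2 (2.34 ± 0.08), GPR65 (1.97 ± 0.07), TREM1 (1.92 ± 0.07), a receptor of activated myeloid cells, NBEAP1 (1.83 ± 0.22) and ARID5B (1.62 ± 0.11) followed. The largest falls were PRTN3 (-2.21 ± 0.08), AZU1 (-2.06 ± 0.05), CEACAM8 (-1.88 ± 0.14), CEACAM6 (-1.42 ± 0.07) and CFD (-1.34 ± 0.06). TSPOAP1 (-1.24 ± 0.05), TASL (-1.16 ± 0.06), TMEM217 (-1.16 ± 0.10), TMEM87A (-1.15 ± 0.05) and KIF20A (-1.12 ± 0.07) followed. Altogether 1553 genes rose and 1974 fell, but with cyclic loess 1881 rose and 1781 fell. Interferon-stimulated genes rose in 24 of 36 (24 adjusted over the list alone), with EIF2AK2 (0.67 ± 0.04), IFI44 (0.78 ± 0.05), HERC5 (0.62 ± 0.05) and DDX60 (0.55 ± 0.06) first, median 0.36 and camera adjusted p = 3.9e-11, and 2 fell. Their mean rise per array over vehicle, 0.323 to 0.357, was smaller than with panobinostat alone, 0.704 to 0.803. Mitosis genes fell in 26 of 34 (27 adjusted over the list alone), with PLK1 (-0.91 ± 0.05), CCNB1 (-0.85 ± 0.05) and CCNB2 (-0.66 ± 0.05) beside KIF20A, median -0.245 and camera adjusted p = 2.4e-13. Their mean fall per array from vehicle, -0.326 to -0.292, was smaller than with azacytidine alone, -0.657 to -0.619. Monocyte and macrophage genes fell in 1 and rose in 11 of 24 (11 adjusted over the list alone), with S100A9 (1.02 ± 0.06) and CD36 (1.07 ± 0.08) beside TREM1 and camera adjusted p = 1.6e-05. Inflammatory and NF-kappa-B genes fell in 2 and rose in 10 of 21 (11 adjusted over the list alone), with CCL20 (1.48 ± 0.10), CXCL8 (0.71 ± 0.05) and CCL2 (0.58 ± 0.05) among the first and camera adjusted p = 5.7e-04. Granulocyte genes rose in 2 and fell in 9 of 17 (9 adjusted over the list alone), with camera adjusted p = 0.00127, and adjusted p = 0.0753 with an estimated correlation. DNA replication genes fell in 1 and rose in 16 of 25 (18 adjusted over the list alone), with GINS4 (0.53 ± 0.05), MCM10 (0.44 ± 0.05), MCM3 (0.36 ± 0.04) and CCNE1 (0.59 ± 0.07) first. Their camera adjusted p was 1.4e-07, and adjusted p = 0.0753 with an estimated correlation. AP-1 and immediate early genes were called upward, where 11 of 27 rose (11 adjusted over the list alone) and 1 fell, with camera adjusted p = 5.7e-04, and adjusted p = 0.0756 with an estimated correlation.

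The departure from additivity was widest in AML-193, with 580 genes, 365 above the sum of the single effects and 215 below it. Mitosis genes lay above the sum in 30 of 34 (33 adjusted over the list alone), with MKI67 (0.51 ± 0.05), CKAP2L (0.51 ± 0.05), FOXM1 (0.65 ± 0.07) and NUSAP1 (0.50 ± 0.06) first, median 0.45 and camera adjusted p = 1.2e-46. Interferon-stimulated genes lay below it in 18 of 36 (28 adjusted over the list alone), with EIF2AK2 (-0.58 ± 0.06), RIGI (-0.67 ± 0.08), DDX60 (-0.59 ± 0.08) and IRF7 (-0.71 ± 0.10) first, median -0.33 and camera adjusted p = 7.4e-26. Granulocyte genes lay above it in 8 of 17 (8 adjusted over the list alone), with CEACAM8 (1.43 ± 0.19), MPO (0.97 ± 0.10), PRTN3 (0.95 ± 0.11) and AZU1 (0.76 ± 0.08) first and camera adjusted p = 3.2e-06. DNA replication genes lay above it in 9 of 25 (20 adjusted over the list alone), led by RRM2 (0.50 ± 0.06) and TYMS (0.43 ± 0.05), with camera adjusted p = 2.3e-16. Anti-apoptotic genes were called below the sum, where 3 of 14 passed (4 adjusted over the list alone) and 1 passed above, with camera adjusted p = 0.00212, and adjusted p = 0.105 with an estimated correlation. Cholesterol synthesis genes were called above the sum, where 3 of 17 passed (6 adjusted over the list alone), with camera adjusted p = 6.8e-04. A call below the sum went to inflammatory and NF-kappa-B genes, where 2 of 21 passed (2 adjusted over the list alone) and 1 passed above, with camera adjusted p = 0.0219, and adjusted p = 0.0638 with an estimated correlation. Metallothionein genes were called below the sum, where 2 of 8 passed (2 adjusted over the list alone), with camera adjusted p = 0.0307, and adjusted p = 0.128 with an estimated correlation. Monocyte and macrophage genes were called below the sum, where 4 of 24 passed (8 adjusted over the list alone), with camera adjusted p = 0.0024. A call below the sum went to MYC targets and ribosome biogenesis genes, where 1 of 26 passed (7 adjusted over the list alone), with camera adjusted p = 4.6e-05, and adjusted p = 0.161 with an estimated correlation. Of single genes, SNAR-C1 (1.42 ± 0.22), SNAR-H (1.26 ± 0.29) and SNAR-B1 (1.21 ± 0.20), uncertain as copies, lay furthest above beside CEACAM8 and MPO. CD180 (-1.41 ± 0.12), GPR34 (-1.24 ± 0.16), AQP9 (-1.15 ± 0.13), GPR82 (-0.98 ± 0.20) and CD101 (-0.93 ± 0.09) lay furthest below. The combination differed from azacytidine alone in 2828 genes, with ENPP2 (2.45 ± 0.08), GPR65 (1.86 ± 0.07), SNAR-B1 (1.75 ± 0.14), an uncertain copy, NBEAP1 (1.67 ± 0.22) and ARID5B (1.65 ± 0.11) highest. AQP9 (-2.17 ± 0.09), an aquaglyceroporin, PRTN3 (-1.34 ± 0.08), TGM5 (-1.32 ± 0.06), GPR34 (-1.07 ± 0.11) and AZU1 (-1.0 ± 0.05) were lowest. It differed from panobinostat alone in 1230 genes, with the uncertain copies SNAR-B1 (2.59 ± 0.14), SNAR-C1 (2.22 ± 0.15), SNAR-D (1.83 ± 0.17) and SNAR-H (1.80 ± 0.21) and then TTC14 (1.03 ± 0.08) highest. The lowest were IFIT1 (-1.21 ± 0.14), TASL (-0.96 ± 0.06), CD180 (-0.91 ± 0.09), RIGI (-0.85 ± 0.05) and KIF20A (-0.83 ± 0.07). With only the 2 groups compared, the count against panobinostat was 787, and with all 60 arrays in 1 fit the departure count was 1034.

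**Figure D2:**
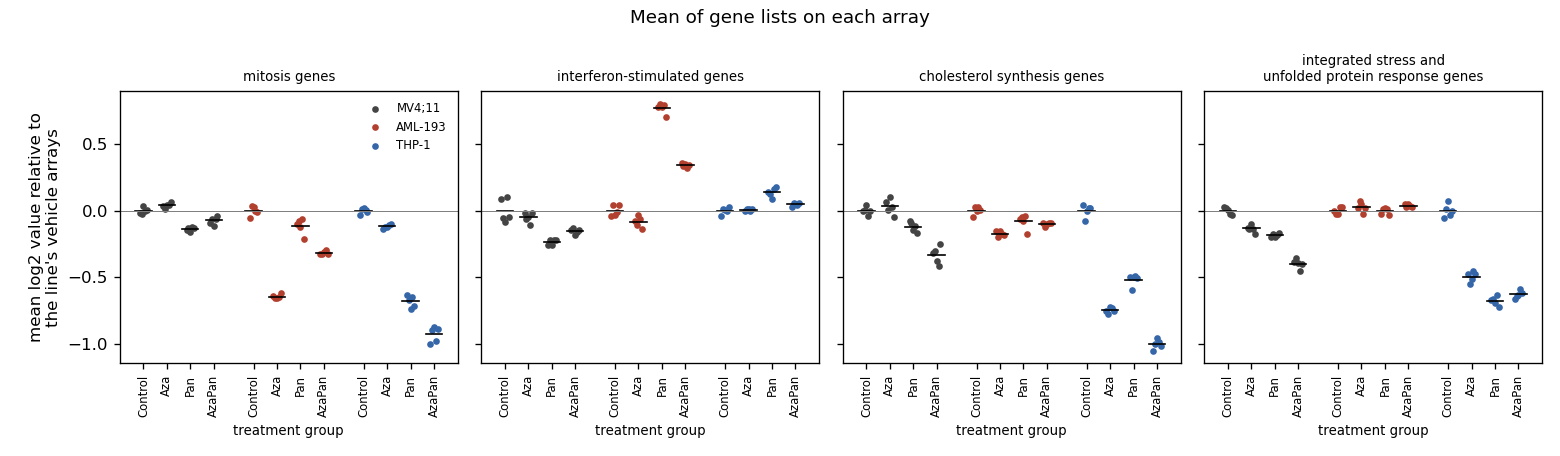
Mean log2 value of the measured members of 4 gene lists on each array, relative to the mean of the line's vehicle arrays, for the 4 groups of each line (points, 5 arrays per group, bars at group means). In AML-193 the mitosis points lie lowest with azacytidine and the interferon points highest with panobinostat, and in THP-1 the cholesterol synthesis points lie lowest with the combination.

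In THP-1, azacytidine lowered genes of cholesterol synthesis and the stress response. HMGCS1 (-1.40 ± 0.05), DHCR7 (-1.26 ± 0.06), the last enzyme of cholesterol synthesis, MSMO1 (-1.22 ± 0.05), HSD17B7 (-1.04 ± 0.09), STARD4 (-0.96 ± 0.04) and ACAT2 (-0.95 ± 0.05) belong to the cholesterol list. That list fell in 16 of 17 members (16 adjusted over the list alone), with a median of -0.75 and camera adjusted p = 3.6e-33. C3 (-1.40 ± 0.05), a complement component, PSAT1 (-1.13 ± 0.06), an enzyme of serine synthesis, SCD (-0.99 ± 0.05), a fatty acid desaturase, and TMEM71 (-0.98 ± 0.08) were the other large falls. The largest rises were small, SNAR-H (0.74 ± 0.11), an uncertain copy, CD1B (0.67 ± 0.10), UBR4 (0.59 ± 0.03), TNF (0.58 ± 0.06) and PAX8-AS1 (0.57 ± 0.07). NOL6 (0.55 ± 0.05), SLAMF8 (0.55 ± 0.05), GPATCH4 (0.54 ± 0.05), SNAR-D (0.53 ± 0.07), also an uncertain copy, and NOLC1 (0.51 ± 0.07) followed. Of 12974 genes, 1220 rose and 1113 fell, but with cyclic loess 1030 rose and 1289 fell. Integrated stress and unfolded protein response genes rose in 1 and fell in 19 of 21 (19 adjusted over the list alone), with PSAT1, PHGDH (-0.89 ± 0.05), the first enzyme of serine synthesis, SESN2 (-0.91 ± 0.06) and DDIT4 (-0.75 ± 0.05) first, median -0.50 and camera adjusted p = 5.9e-25. MYC targets and ribosome biogenesis genes rose in 23 of 26 (24 adjusted over the list alone), with CTPS1 (0.40 ± 0.04), GRWD1 (0.36 ± 0.04) and BOP1 (0.44 ± 0.05) beside NOLC1 and camera adjusted p = 2.8e-18. Heat shock genes rose in 9 of 13 (9 adjusted over the list alone), with HSPH1 (0.49 ± 0.04), HSPA4 (0.36 ± 0.03), HSPA1A (0.41 ± 0.04) and HSPA1B (0.38 ± 0.04) first and camera adjusted p = 1.4e-10. The last pair are near-identical copies. HLA class I and antigen processing genes fell in 4 of 6 (5 adjusted over the list alone), TAPBP (-0.33 ± 0.03), CALR (-0.32 ± 0.03), CANX (-0.20 ± 0.03) and ERAP1 (-0.21 ± 0.05), with camera adjusted p = 5.1e-05. Only 6 of the 19 genes of that list were named, and none of the 4 that fell was an HLA gene. Mitosis genes rose in 1 and fell in 13 of 34 (15 adjusted over the list alone), with camera adjusted p = 4.1e-06, and adjusted p = 0.15 with an estimated correlation. DNA replication genes rose in 16 of 25 (18 adjusted over the list alone), with camera adjusted p = 2.6e-08, and adjusted p = 0.138 with an estimated correlation. Granulocyte genes were called downward, where 5 of 16 fell (6 adjusted over the list alone), with camera adjusted p = 0.00191. Homologous recombination and Fanconi genes were called upward, where 3 of 14 rose (3 adjusted over the list alone), with camera adjusted p = 0.0203, and adjusted p = 0.298 with an estimated correlation. HOXA cluster and MLL-fusion target genes were called downward, where 4 of 14 fell (4 adjusted over the list alone), with camera adjusted p = 0.0203, and adjusted p = 0.073 with an estimated correlation.

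Panobinostat in THP-1 lowered all 34 measured mitosis genes as well as stress response and cholesterol synthesis genes. The mitosis list had a median of -0.69 and camera adjusted p = 1.8e-49, with 34 members passing adjusted over the list alone and PLK1 (-0.87 ± 0.04), TOP2A (-0.75 ± 0.03), BUB1 (-0.87 ± 0.04) and KIF20A (-0.95 ± 0.05) first. The largest falls were PSAT1 (-1.67 ± 0.06), SPP1 (-1.47 ± 0.10), the secreted protein osteopontin, HIF1A-AS2 (-1.36 ± 0.15), PHGDH (-1.23 ± 0.05) and AARS1 (-1.12 ± 0.04), alanyl-tRNA synthetase. HMGCS1 (-1.11 ± 0.05), KIF14 (-1.07 ± 0.06), ATF5 (-1.07 ± 0.06), IQGAP3 (-1.02 ± 0.05) and WARS1 (-1.01 ± 0.05) followed. The largest rises were CAPN6 (1.56 ± 0.10), CLDN10 (1.44 ± 0.08), a tight junction protein, CLIC6 (1.36 ± 0.13), ADAM28 (1.29 ± 0.07) and VAT1L (1.19 ± 0.05). NME8 (1.17 ± 0.08), STAP1 (1.13 ± 0.08), DPP4 (1.05 ± 0.08), a cell-surface peptidase, ENPP5 (1.04 ± 0.10) and SUCNR1 (0.99 ± 0.10), the succinate receptor, followed. Of 12974 genes, 1287 rose and 1438 fell. Integrated stress and unfolded protein response genes fell in 18 of 21 (19 adjusted over the list alone), with a median of -0.67 and camera adjusted p = 1.0e-26. Cholesterol synthesis genes fell in 15 of 17 (16 adjusted over the list alone), with ACAT2 (-0.76 ± 0.05), MSMO1 (-0.81 ± 0.05) and STARD4 (-0.56 ± 0.04) beside HMGCS1, median -0.57 and camera adjusted p = 1.6e-19. Homologous recombination and Fanconi genes fell in 10 of 14 (11 adjusted over the list alone), RAD54L (-0.37 ± 0.06) and CHEK1 (-0.28 ± 0.05) among the first, with camera adjusted p = 3.4e-06. Interferon-stimulated genes fell in 3 and rose in 14 of 35 (17 adjusted over the list alone), with UBE2L6 (0.64 ± 0.05), IFITM1 (0.45 ± 0.04), EIF2AK2 (0.43 ± 0.05) and SP110 (0.41 ± 0.05) first and camera adjusted p = 1.0e-04. Monocyte and macrophage genes fell in 3 and rose in 10 of 27 (10 adjusted over the list alone), APOE (0.47 ± 0.05) and VCAN (0.43 ± 0.06) first, with camera adjusted p = 0.012, and adjusted p = 0.0811 with an estimated correlation. DNA replication genes were called downward, where 7 of 25 fell (8 adjusted over the list alone) and 1 rose, with camera adjusted p = 5.6e-04, and adjusted p = 0.384 with an estimated correlation. Heat shock genes were called downward, where 4 of 13 fell (6 adjusted over the list alone), with camera adjusted p = 0.037, and adjusted p = 0.296 with an estimated correlation. A call upward went to MYC targets and ribosome biogenesis genes, where 8 of 26 rose (12 adjusted over the list alone) and 2 fell, with camera adjusted p = 5.2e-04, and adjusted p = 0.246 with an estimated correlation.

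The combination changed more genes in THP-1 than either single drug, 2336 upward and 1912 downward, and 55 of the falls were 2-fold or more. Cholesterol synthesis genes fell in 16 of 17 (16 adjusted over the list alone), with a median of -1.07 and camera adjusted p = 2.7e-24. HMGCS1 (-1.94 ± 0.05), MSMO1 (-1.62 ± 0.05), DHCR7 (-1.47 ± 0.06) and INSIG1 (-1.45 ± 0.06) were among the 10 largest falls of any gene. SPP1 (-1.90 ± 0.10), PSAT1 (-1.46 ± 0.06), GPR18 (-1.40 ± 0.10), KIF14 (-1.38 ± 0.06), KIF20A (-1.37 ± 0.05) and IQGAP3 (-1.34 ± 0.05) were the others. The largest rises were VAT1L (1.74 ± 0.05), CLIC6 (1.62 ± 0.13), CLDN10 (1.53 ± 0.08), SYT11 (1.41 ± 0.07), a synaptotagmin, and EPHB1 (1.32 ± 0.05), an ephrin receptor. CAPN6 (1.23 ± 0.10), ENPP5 (1.08 ± 0.10), PCNX2 (1.08 ± 0.05), SNAR-H (1.06 ± 0.11), an uncertain copy, and BCL9 (1.01 ± 0.08) followed. All 34 mitosis genes fell, PLK1 (-1.15 ± 0.04), CCNA2 (-1.11 ± 0.04) and TOP2A (-0.97 ± 0.03) among the first, with 34 adjusted over the list alone, a median of -0.94 and camera adjusted p = 2.7e-45. Integrated stress and unfolded protein response genes fell in 19 of 21 (19 adjusted over the list alone), with PHGDH (-1.14 ± 0.05), TRIB3 (-0.80 ± 0.05) and XBP1 (-0.64 ± 0.04) beside PSAT1, median -0.64 and camera adjusted p = 9.6e-20. MYC targets and ribosome biogenesis genes rose in 23 of 26 (23 adjusted over the list alone), with NAT10 (0.50 ± 0.03), MYC (0.55 ± 0.04), BOP1 (0.46 ± 0.05) and NOP58 (0.32 ± 0.04) first and camera adjusted p = 2.8e-12, and 2 fell. Metallothionein genes fell in 4 of 9 (6 adjusted over the list alone), MT2A (-1.01 ± 0.10), MT1F (-0.74 ± 0.06), MT1G (-0.67 ± 0.11) and MT1E (-0.35 ± 0.07), with camera adjusted p = 0.00492. Homologous recombination and Fanconi genes fell in 9 of 14 (11 adjusted over the list alone), with camera adjusted p = 8.8e-05, and adjusted p = 0.0692 with an estimated correlation. DNA replication genes were called downward, where 11 of 25 fell (13 adjusted over the list alone) and 1 rose, with camera adjusted p = 4.5e-04, and adjusted p = 0.434 with an estimated correlation.

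Relative to azacytidine alone, 3090 genes differed in THP-1 with the combination, and relative to panobinostat alone 2290. Against azacytidine, CLIC6 (1.72 ± 0.13), CLDN10 (1.61 ± 0.08), VAT1L (1.49 ± 0.05), CAPN6 (1.45 ± 0.10) and GXYLT2 (1.23 ± 0.09) were higher. SPP1 (-2.17 ± 0.10), NDC80 (-1.12 ± 0.06), a kinetochore protein, KIF20A (-1.10 ± 0.05), CCNB1 (-1.09 ± 0.05) and KNL1 (-1.07 ± 0.05) were lower. Against panobinostat, UBR4 (0.85 ± 0.03), SYT11 (0.64 ± 0.07), ZNF718 (0.62 ± 0.10), COX8C (0.56 ± 0.08) and VAT1L (0.55 ± 0.05) were higher. C3 (-1.46 ± 0.05), STXBP5-AS1 (-1.06 ± 0.12), MAP2K6 (-0.95 ± 0.10), CD84 (-0.94 ± 0.05) and EVI2B (-0.91 ± 0.06) were lower. The combination departed from the sum of the single effects in 303 genes, 222 above it and 81 below it. PSAT1 (1.34 ± 0.08), ULBP1 (1.07 ± 0.10), an NKG2D ligand, PHGDH (0.98 ± 0.07), AARS1 (0.98 ± 0.06) and ASNS (0.94 ± 0.11), asparagine synthetase, lay furthest above. KRT8P41 (-0.77 ± 0.20), SPP1 (-0.70 ± 0.14), IFI44 (-0.68 ± 0.10), CD1B (-0.63 ± 0.15) and IL7R (-0.61 ± 0.14) lay furthest below. Integrated stress and unfolded protein response genes lay above the sum in 14 of 21 (17 adjusted over the list alone, with 1 below), median 0.56 and camera adjusted p = 8.3e-35, WARS1 (0.87 ± 0.08) and ATF4 (0.51 ± 0.05) among the first. Cholesterol synthesis genes lay above it in 8 of 17 (10 adjusted over the list alone), HMGCS1 (0.56 ± 0.07) and HSD17B7 (0.79 ± 0.12) among them, with camera adjusted p = 9.0e-13. DNA replication genes lay below it in 5 of 25 (16 adjusted over the list alone), TYMS (-0.49 ± 0.06), PCNA (-0.38 ± 0.07), CCNE2 (-0.43 ± 0.08) and CDC6 (-0.37 ± 0.08) first, with camera adjusted p = 3.8e-15. Heat shock genes were called below the sum, where 0 of 13 passed (0 adjusted over the list alone), with camera adjusted p = 0.0141, and adjusted p = 0.207 with an estimated correlation. Homologous recombination and Fanconi genes were called below the sum, where 0 of 14 passed (0 adjusted over the list alone), with camera adjusted p = 0.00381, and adjusted p = 0.193 with an estimated correlation. HOXA cluster and MLL-fusion target genes were called above the sum, where 1 of 14 passed (2 adjusted over the list alone), with camera adjusted p = 0.00275. A call below the sum went to interferon-stimulated genes, where 3 of 35 passed (4 adjusted over the list alone), with camera adjusted p = 4.0e-04. Mitosis genes were called below the sum, where 4 of 34 passed (8 adjusted over the list alone), with camera adjusted p = 7.8e-09, and adjusted p = 0.0813 with an estimated correlation. A call below the sum went to MYC targets and ribosome biogenesis genes, where 0 of 26 passed (0 adjusted over the list alone), with camera adjusted p = 0.0102, and adjusted p = 0.372 with an estimated correlation. Nucleoside uptake and metabolism genes were called below the sum, where 2 of 16 passed (4 adjusted over the list alone), with camera adjusted p = 0.00361, and adjusted p = 0.139 with an estimated correlation. With a trended, robust variance the departure count was 457. KRT8P41 did not pass with no filter (adjusted p = 0.0587) or in 17 of the 20 fits with 1 array left out, IL7R in 9 of those fits and CD1B in 3, and CD1B did not pass with all 60 arrays in 1 fit (0.0691).

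Genes that both single drugs moved in 1 direction numbered 128 in MV4;11, 624 in AML-193 and 678 in THP-1, and 33, 190 and 309 went opposite ways. Independent lists of the same sizes would share 31, 191.2 and 244.4 genes in direction. These numbers take no account of genes that are easier to call in any comparison. Both comparisons use the same vehicle arrays. With those arrays split into 2 and 3, the counts were 4 to 53, 276 to 348 and 332 to 387. These fits hold fewer vehicle arrays, so their counts cannot be set against the numbers expected from the full fits. The covariance of the log2 fold changes across genes was 0.0053, 0.0113 and 0.007, beside 0.0034, 0.0035 and 0.0028 in 100 simulations of unchanged groups against those arrays. The matching correlations across genes, which are not independent replicates, were 0.261, 0.335 and 0.269. Simulated values were 0.5, 0.499 and 0.5, which the shared vehicle arrays alone produce in unchanged groups of equal size. They therefore do not show that the drugs were less alike than chance. With split vehicle arrays the correlations were 0.034 to 0.126, 0.092 to 0.239 and 0.124 to 0.154. In MV4;11 each array left out lowered the shared count, to 78 and 81 without Control replicates 1 and 3 and 82 without Aza replicate 5. It was 71 there with only the groups compared, 229 with all 60 arrays in 1 fit and 210 with a trended, robust variance.

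A core of genes answered the combination alike in the 3 lines. Of 12276 genes tested in each, 214 rose and 244 fell in all, against 79.5 expected of independent lists in total. The 5 rises with the largest minimum change over MV4;11, AML-193 and THP-1, in that order, were ADAM28 (1.24, 1.50 and 0.97), SYT11 (0.80, 0.80 and 1.41), CCL2 (1.58, 0.58 and 0.78), CFAP263 (0.65, 0.57 and 0.93) and GDAP1 (0.60, 0.54 and 0.68). Next were DUSP4, ARL6, BCL9, EXTL2 and DPP4. ADAM28, a membrane protease, led the rises, and DUSP4 is a phosphatase of MAP kinases. The 5 falls with the largest minimum change over MV4;11, AML-193 and THP-1, in that order, were PILRA (-0.61, -0.54 and -0.53), ERN1 (-0.86, -0.54 and -0.52), IQGAP3 (-0.67, -0.52 and -1.34), RGCC (-0.50, -1.02 and -0.50) and UBA7 (-0.49, -0.72 and -0.55). Next were CPNE2, PHF19, TTC9C, MSRA and INSIG1. ERN1 encodes the stress sensor IRE1, and INSIG1 restrains cholesterol synthesis. A further 343 genes changed in all 3 lines but not in 1 direction. Panobinostat alone moved 374 genes in 1 direction in all lines, against 33.8 expected, and azacytidine alone 27, against 1.7.

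The lines differed from one another in many genes of the combination effect, tested as the difference of effects in 1 fit of both lines. MV4;11 and AML-193 differed in 3279 of 13201 genes, MV4;11 and THP-1 in 3089 of 13246, and AML-193 and THP-1 in 4121 of 13284. Opposite changes, each passing in its own line, were seen in 430, 440 and 685 genes. Of the combination effects in MV4;11 minus those in AML-193, the largest were TMT1B (3.12 ± 0.08), VAT1L (2.94 ± 0.11) and CEACAM8 (2.16 ± 0.19), and the most negative CXCL8 (-2.94 ± 0.16), CCL7 (-2.87 ± 0.22) and SNAR-B1 (-2.74 ± 0.16). Of the combination effects in MV4;11 minus those in THP-1, the largest were TMT1B (2.73 ± 0.07), GPC3 (2.18 ± 0.10) and GPRIN3 (1.86 ± 0.19), and the most negative ALOX12 (-2.17 ± 0.09), CXCL8 (-1.97 ± 0.20) and TNF (-1.57 ± 0.09). Of the combination effects in AML-193 minus those in THP-1, the largest were CCL7 (2.49 ± 0.23), ENPP2 (2.31 ± 0.11) and SPP1 (2.19 ± 0.13), and the most negative PRTN3 (-2.12 ± 0.08), AZU1 (-2.01 ± 0.06) and CEACAM8 (-1.82 ± 0.20). Gene lists differed too, in tests added after the lists had been seen within lines. The fall of mitosis genes was deeper in THP-1 than in MV4;11 (median difference 0.87, 33 of 34 members, camera adjusted p = 6.6e-55) and AML-193 (0.60, 30 of 34 members, camera adjusted p = 1.5e-29). Cholesterol synthesis genes were also lower in THP-1 than in MV4;11 (median difference 0.73, camera adjusted p = 3.4e-18) and AML-193 (1.00, camera adjusted p = 1.8e-21). Interferon-stimulated genes were lower in MV4;11 than in AML-193 (median difference -0.43, camera adjusted p = 7.3e-12), as were inflammatory genes (-0.46, camera adjusted p = 5.5e-10). Of 28 lists tested, 10, 13 and 14 passed for MV4;11 and AML-193, MV4;11 and THP-1, and AML-193 and THP-1, and 7, 10 and 8 with an estimated correlation. Doses and growth media differed between lines, so these differences are between treated lines as handled, not between lines at 1 dose.

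Of the 28 lists with enough measured members, 9 were called in no comparison against vehicle and no departure. These were cancer-testis and germline genes, genes methylated and silenced in leukaemia, DNA methylation enzymes and readers, histone deacetylase genes, and pro-apoptotic genes. The marker lists of erythroid and megakaryocyte cells, of T, B and NK lymphocytes, of fibroblasts, endothelium and epithelium, and of neurons were not called either. Their lowest camera adjusted p was 0.0829, for neuron genes. Of 51 cancer-testis and germline genes, 15 were named and 7 to 9 were measured per line, so the lack of a call covers only those. Of them, PRAME (0.36 ± 0.05) rose with azacytidine in THP-1. The HLA class II list had 1 named member and the replication-independent histone list 0, so neither was tested.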

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

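The gene list tests between lines, the test of the 5 SNAR rows that rose, the tests of AML-193 without 2 arrays and of genes of the same level, and the test of THP-1 with each array left out in turn were chosen only after the results were seen.

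Chance regrouping of the arrays is argued against for each count of changed genes, since in every comparison 1 of 100 groupings, the real one, gave as many genes. The others were splits of the 10 arrays for drug comparisons, random assignments of deviations from additivity to the 20 arrays for departures, and random line labels within a treatment, after each line's own gene means were taken off, for lines. Splits that mix the 2 groups take a drug effect into their spread, which lowers their counts. No such grouping can tell a drug effect from another difference between whole groups, such as one of culture or array batch. In MV4;11 the real counts and the highest of the other groupings were 284 and 1 for azacytidine, 3067 and 2 for panobinostat, and 3629 and 4 for the combination. Against azacytidine alone they were 3379 and 186, against panobinostat alone 377 and 4, and for the departure from additivity 35 and 2. In AML-193 they were 1627 and 45, 2893 and 552, 3527 and 936, 2828 and 4, 1230 and 118, and 580 and 1, in the same order. In THP-1 they were 2333 and 1, 2725 and 2, 4248 and 423, 3090 and 55, 2290 and 20, and 303 and 1. For the combination effect between lines, 3279 genes stood against 844 for MV4;11 and AML-193, 3089 against 581 for MV4;11 and THP-1, and 4121 against 1273 for AML-193 and THP-1.

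The effect of the combination differed between lines by a test of the difference itself. Between MV4;11 and AML-193 the effect on TMT1B was higher by 3.12, on VAT1L by 2.94 and on CEACAM8 by 2.16 in MV4;11, and the differences of CXCL8, CCL7 and the uncertain copy SNAR-B1 were -2.94, -2.87 and -2.74. Between MV4;11 and THP-1 the differences were 2.73 for TMT1B, 2.18 for GPC3, 1.86 for GPRIN3, -2.17 for ALOX12, -1.97 for CXCL8 and -1.57 for TNF. Between AML-193 and THP-1 they were 2.49 for CCL7, 2.31 for ENPP2, 2.19 for SPP1, -2.12 for PRTN3, -2.01 for AZU1 and -1.82 for CEACAM8. The median difference of inflammatory genes between MV4;11 and AML-193 was -0.46 and that of interferon-stimulated genes -0.43. Mitosis genes differed from THP-1 by medians of 0.87 in MV4;11 and 0.60 in AML-193, and cholesterol synthesis genes by 0.73 and 1.00. Dose and medium differed between lines as well, and they cannot be set apart from the line by these groups.

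Single arrays lay far from the other 4 of their group for 51 of 1014 pairs of a named gene and a group, or 5%, where chance marks about 1 in 20 groups. The measure is the gap to the nearest array over the range of the group, with a bound of 0.71. In the MV4;11 Control group these were CCDC50 (replicate 1 lowest, 0.836), DNMT1 (replicate 5 lowest, 0.786) and GDAP1 (replicate 5 highest, 0.721). In the MV4;11 Aza group these were RGS16 (replicate 4 lowest, 0.801). In the MV4;11 Pan group these were BMP2 (replicate 1 lowest, 0.8), CCL5 (replicate 2 lowest, 0.789), GAS6-DT (replicate 2 highest, 0.754) and VIT (replicate 2 highest, 0.749). In the MV4;11 AzaPan group these were ARL6 (replicate 3 lowest, 0.862), CFAP263 (replicate 5 highest, 0.752), CPNE2 (replicate 2 highest, 0.716) and ERN1 (replicate 2 lowest, 0.726).

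In the other lines the same measure marked these genes. In the AML-193 Control group these were CCL20 (replicate 2 highest, 0.715), DNMT1 (replicate 1 lowest, 0.814), DPP4 (replicate 2 highest, 0.806), FOXM1 (replicate 1 lowest, 0.723), HDAC3 (replicate 1 lowest, 0.726), KIF20A (replicate 2 highest, 0.743), NXF3 (replicate 4 highest, 0.715) and TMEM217 (replicate 5 highest, 0.785). In the AML-193 Aza group these were CCNB1 (replicate 3 lowest, 0.763), SNAR-B1 (replicate 3 lowest, 0.804) and SNAR-C1 (replicate 3 lowest, 0.77). In the AML-193 Pan group these were BARD1 (replicate 5 lowest, 0.745), CD86 (replicate 5 lowest, 0.772), DNMT1 (replicate 5 highest, 0.732), DNMT3A (replicate 5 highest, 0.728) and PRTN3 (replicate 5 lowest, 0.73). In the AML-193 AzaPan group these were CPNE2 (replicate 2 lowest, 0.818), CXCL8 (replicate 4 highest, 0.78) and IRF7 (replicate 2 highest, 0.799). In the THP-1 Control group these were GPR18 (replicate 4 highest, 0.747), MT2A (replicate 2 lowest, 0.774), PHF19 (replicate 3 lowest, 0.828), STAP1 (replicate 1 lowest, 0.795) and TAPBP (replicate 1 highest, 0.763). In the THP-1 Aza group these were GRWD1 (replicate 3 lowest, 0.713), IL7R (replicate 4 highest, 0.726), MSMO1 (replicate 3 highest, 0.726), NOL6 (replicate 2 highest, 0.741) and ULBP1 (replicate 5 highest, 0.713). In the THP-1 Pan group these were CLIC6 (replicate 1 highest, 0.766), HDAC1 (replicate 2 lowest, 0.802), HMGCS1 (replicate 2 lowest, 0.731) and STXBP5-AS1 (replicate 2 lowest, 0.882). In the THP-1 AzaPan group these were ADAM28 (replicate 5 highest, 0.743), ATF4 (replicate 2 highest, 0.948), C3 (replicate 2 lowest, 0.88), DNMT1 (replicate 3 highest, 0.749), ENPP2 (replicate 5 lowest, 0.776) and PILRA (replicate 4 highest, 0.774).

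Of 24 pairs of an array-wide measure and a group, 4 lay past the same bound. The median of AML-193 Control replicate 1 was the highest of its group (0.738). The correlation with the group was lowest for MV4;11 Pan replicate 2 (0.8), AML-193 Control replicate 1 (0.8) and AML-193 Pan replicate 5 (0.714). AML-193 Pan replicate 5 held 6 of the marked values and AML-193 Control replicate 1 held 5, array-wide measures included.

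In AML-193, 5 of 8 SNAR rows rose with the combination, with a median of 1.4 over the 8. A shift of short RNAs in general is argued against by the 627 other short RNA genes, whose median change was 0 and whose upper quartile was 0.126. Over all 8 rows the median correlation of deviations from group means was 0.06, below the bound of 0.2 that had been set for signal shared between near-identical copies. Noise of single rows also lowers this value, and the rows' spread between replicates was 2.23 times the median of all genes. The value therefore does not decide on sharing. That bound took in 3 rows that did not rise, and over the 5 that rose, a restriction made only after the first value was known, the correlation was 0.24, above the bound, so sharing among those rows stays open. Of the 5, SNAR-B1, SNAR-C1, SNAR-D and SNAR-H changed by 0.38, 0.33, 0.34 and 0.36 in MV4;11 and 0.97, 0.94, 0.95 and 1.06 in THP-1. SNAR-G2 changed by 0.01 and 0.46. The drug combination as the cause was not tested further, and which copies changed cannot be told apart here.

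Mitosis genes in AML-193 fell less with the combination than the sum of the single drugs, with a median departure of 0.45. Their mean fall per array with the combination, -0.326 to -0.292, was also smaller than with azacytidine alone, -0.657 to -0.619. It was larger than with panobinostat alone, -0.213 to -0.06. Arrays that stood apart are argued against, since without Control replicate 1 and Pan replicate 5 the departure still passed above 0 in 31 of 34 genes, with a median of 0.43. A shift of the arrays at the level of these genes is argued against too, since 655 other genes of the same level had a median departure of 0.01 and an upper quartile of 0.12. With cyclic loess the median of the mitosis genes was 0.45, but that setting moved the departures of other genes by a median of only 0.01, less than had been asked of it in advance, so that run alone decides nothing. The departure is itself the less than additive effect, and what causes it in the cells was not tested.

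Stress response genes in THP-1 also fell less with the combination than the sum of the single drugs, 14 of 21 passing. Values near the floor of the arrays are argued against, since 0 of 21 members had an additive level below the 30th percentile of 4.59, and the median additive level was 6.79. A single array is argued against too, since with each of the 20 arrays left out in turn the lowest number of members passing above 0 was 14 and the lowest median departure 0.53. What causes this less than additive fall in the cells was not tested.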

How the results depend on the processing

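The removal of AML-193 Control replicate 1 and Pan replicate 5 together was chosen only after the data were seen. No called list, and no named gene that had passed, turned its direction under any alternative run. The larger of rises and falls turned in 5 runs. With cyclic loess, rises and falls numbered 1881 and 1781 for the combination in AML-193, 1713 and 1288 for the combination against azacytidine there, 1030 and 1289 for azacytidine in THP-1, and 1099 and 1127 for the combination against panobinostat there. With array weights the combination against panobinostat in AML-193 gave 779 and 952. All 25 counts stayed within 1.5 times their value with no filter, with the filter at the 50th percentile, median centring, cyclic loess, array weights and the mean of a gene's rows.

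With only the groups compared, MV4;11 gave 138 genes for azacytidine, 171 for the combination against panobinostat and 71 shared by both drugs, and AML-193 gave 787 for the combination against panobinostat. With all 60 arrays in 1 fit, MV4;11 gave 514, 601 and 229 in that order and 81 for the departure, and the AML-193 departure was 1034. With a trended, robust variance MV4;11 gave 482 for azacytidine, 210 shared and 74 for the departure, and the THP-1 departure was 457. The cause was not tested. The replicate numbers did not pair the arrays, since same-number correlations of deviations ran from -0.103 to 0.148 in MV4;11, -0.313 to 0.245 in AML-193 and -0.134 to 0.167 in THP-1, with 3, 2 and 1 of 30 over 0.1. With the replicate block the MV4;11 departure was 22, and the other 24 counts stayed within 1.5 times.

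With 1 array left out, MV4;11 gave 167 to 228 genes for azacytidine, 18 to 31 for the departure and 78 to 112 shared by both drugs, with fewer arrays in each fit. The lowest came without Control replicate 1, Pan replicate 4 and Control replicate 1. The other 22 counts stayed within 1.5 times. Of 104 called lists, 47 were lost with an estimated correlation, 1 with fry and 1 with the replicate block, AP-1 and immediate early genes with azacytidine in MV4;11 (adjusted p = 0.0608). Leaving out 1 array lost 34 of 1310 list calls. Without both AML-193 arrays all 8 counts stayed within 1.5 times and 39 of 40 list calls passed, the exception being anti-apoptotic genes with azacytidine (adjusted p = 0.104). Of the values of genes named in the text, at most 14 of 578 lost their call under 1 of the other settings, with the replicate block, and leaving out 1 array lost 159 of 6550. Signal over background limits what the fits can show, and genes above the 30th percentile on fewer than 5 of a line's 20 arrays were left out of them.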

Other observations

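The tests of rows not named here were chosen only after the results of named genes were seen, and the list tests were planned. Azacytidine in AML-193 raised some members of the metallothionein and heat shock lists beside the changes of mitosis genes. Metallothionein genes rose in 3 of 8 (4 adjusted over the list alone), MT1X (0.72 ± 0.06), a zinc-binding protein, MTF1 (0.34 ± 0.05), the metal-responsive transcription factor, and MT1E (0.31 ± 0.10), with camera adjusted p = 0.00124. MT1E did not pass with no filter (adjusted p = 0.0545), median centring (0.0681), only the groups compared (0.0827) or in 6 of 10 fits with 1 array left out, nor without both Control replicate 1 and Pan replicate 5 (0.0791). Heat shock genes fell in 1 and rose in 6 of 12 (8 adjusted over the list alone), with HSPH1 (0.44 ± 0.05), BAG3 (0.29 ± 0.06), HSPD1 (0.24 ± 0.05) and STIP1 (0.24 ± 0.06) first and camera adjusted p = 0.00956. STIP1 did not pass with only the groups compared (adjusted p = 0.0535). MYC targets and ribosome biogenesis genes rose in 12 of 26 (16 adjusted over the list alone), ODC1 (0.55 ± 0.04), ornithine decarboxylase, MRTO4 (0.26 ± 0.04), CTPS1 (0.24 ± 0.04) and RRP12 (0.30 ± 0.06) first, with camera adjusted p = 3.5e-09.

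Antigen processing genes fell with the combination in THP-1 in 4 of 6 (4 adjusted over the list alone), TAPBP (-0.56 ± 0.03), CALR (-0.40 ± 0.03), ERAP1 (-0.36 ± 0.05) and CANX (-0.23 ± 0.03), with camera adjusted p = 0.0028. None of these 4 was an HLA gene, and 6 of the list's 19 genes were named. Homologous recombination and Fanconi genes lay above the sum of the single drugs in AML-193 in 5 of 14 (9 adjusted over the list alone), EXO1 (0.43 ± 0.06) and RAD51AP1 (0.46 ± 0.08) first, with camera adjusted p = 1.4e-09.

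Rows that were not named here changed as well. Of 25214 such rows tested in MV4;11, 25169 in AML-193 and 25003 in THP-1, the combination changed 2752, 3332 and 3546. Azacytidine changed 100, 1366 and 1550, and panobinostat 1949, 2437 and 2008. The departure from additivity passed in 0, 310 and 178 by limma.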
